A study of Mus musculus with 78 samples.

How the data were processed

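Soleus RNA from 78 libraries of mice was compared by age, sex, batch and CaAKG feeding. Per the submitters' processing notes, reads were checked with FastQC, aligned with STAR 2.7.11b to mm10 and quantified with RSEM 1.3.3; the annotation release, strand setting and any filter are not given in the sources used here. The authors deposited one table of expected counts for 36904 gene IDs, estimated by RSEM, in which 8.99% of the values in the columns used were not whole (tolerance 1e-06). Expected counts split reads among near-identical genes by estimate, and without a stated strand setting reads of overlapping antisense genes cannot be told apart, so such genes are uncertain. Of the table's columns, 55 match no sample label and were not used.

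The expected counts were rounded to whole numbers. Gene symbols matched 35298 IDs and GENCODE M21 positions (mm10) 35338 IDs; the 1566 IDs with no match held 0.881% of the counts. The 2 libraries of 12-month females whose names share an animal tag were summed to 1 replicate, which leaves 77 replicates; they differed by a chi-square of 46.6 per gene, against a median of 16.9 over pairs within groups, so that they come from 1 animal rests on the tag alone. Replicates are labelled as separate mice, and their numbers were given in accession order, so they pair nothing. The label M28 was read as 28 months of age. Per the design text, mice of 6 and 12 months came from a different supplier than mice of 20 months. Compared pairwise over 12502 genes, within and across groups, the closest of 3003 library pairs differed by a chi-square of 5.45 per gene, where a copy would give 0.

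Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 18218. One edgeR 4.0.16 quasi-likelihood fit (edgeR QL) with TMM factors and a mean for each of the 11 combinations of age, sex, treatment and batch gave 12 comparisons, with Benjamini-Hochberg adjusted p and a threshold of 0.05. All log2 fold changes and adjusted p values of single genes come from this fit unless another tool is named, and CPM are counts scaled per 1e6 of a library, computed here with TMM factors, except the sums of markers and the sex check, which use library totals. The batch comparison and the interaction were fitted in the same model.

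Before the data were examined, 34 gene lists, the comparisons and the alternatives were fixed. Lists were tested with limma camera 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, and repeated with an estimated correlation, with which 0 lists passed in either 28 to 6 month comparison, with CaAKG or between the sexes. Counts adjusted over the list alone adjust p over the members of a list. The genes named in the 4 comparisons with lists were the 8 largest rises and the 8 largest falls among genes past the threshold with a mean of at least 1 CPM in the higher group (without number-only, immunoglobulin, T cell receptor and pseudogene symbols), all that passed where fewer did, and the 3 lowest p where none did; up to 4 members with the smallest p of each described list; 4 myosin genes and Cdkn2a, Cdkn1a and Gdf15 throughout; and 5 sex-linked genes as a check. One gene that this rule names is left out of the text. For the other comparisons, genes already named were reused. The 12 keratinocyte markers were added after the data were seen, as was the limit of 100 CPM.

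Alternatives were DESeq2 1.42.0, limma-voom with quality weights, RLE factors, the mitochondrial genome left out, no filter, a minimum count of 50, only the compared groups in the fit, the replicate block, the animal-tag libraries kept apart, list means as covariates (prior count 2), a test against a fold of 1.2, pooled batches with batch as a term, and leaving out single libraries. Added after the data were seen were fits without the libraries against their sex label, without those with skin or marrow transcripts, without both sets, without single libraries far from their group for Myh4, Cdkn1a and the mitochondrial genome, and with offsets per library from a smooth trend on transcript length and GC (splines of 5 degrees of freedom, known for 97.5% of the genes tested). The correlation of the CaAKG and age changes was set against 100 reassignments of labels, and each count against 100 regroupings of the libraries.

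On simulated counts for the 18218 genes with 200 changed, the edgeR fit recovered, for CaAKG against control, 50.7% of genes changed 1.5-fold, 59.7% changed 2-fold and 81.8% changed 4-fold, with 7.25% of its calls false. For 28 against 6 months in males the shares were 28.4%, 46.3% and 60.6%. For 20 against 6 months in males with a simulated length trend, 3576 unchanged genes were called without the offsets and 19 with them. The simulated trend was built from the same transcript lengths that the offsets use.

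Totals of 19.5 to 81.6 (median 35.2) x 1e6 counts per library, with the mitochondrial genome holding 10.05% to 46.52%, leave genes under a few CPM imprecise, and the spread between mice sets the precision of the others. P values of the edgeR fit rest on the spread between mice within groups of 4 to 12 replicates, pooled over all groups in the fit. They do not rest on the spread within the compared groups alone.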

Results

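Soleus muscle, a postural hindlimb muscle rich in slow fibres, was profiled by bulk RNA sequencing in C57BL/6 mice of both sexes at 6, 12, 20 and 28 months of age. A further group of 28-month males had received calcium alpha-ketoglutarate (CaAKG), a salt of a tricarboxylic acid cycle intermediate, at 2% of the feed. Of the 78 libraries 30 were labelled female and 48 male, in 2 labelled batches. Batch 1 held 4 females and 6 males at 6 months, 6 replicates of each sex at 12 months, 6 females and 9 males at 20 months, and 6 females and 5 males at 28 months. Batch 2 held 7 control females, 10 control males and 12 males on CaAKG, all at 28 months. After a filter on low counts 18218 genes entered the tests. Age and sex comparisons used batch 1 libraries and the CaAKG comparison used batch 2 libraries.

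The transcripts of the sex chromosomes gave a check on the labels. Xist, the noncoding RNA that silences one X chromosome in females, had a median of 121 CPM in the labelled females that matched their label, and Ddx3y, a Y-linked RNA helicase, had a median of 89.9 CPM in the matching males. In 5 libraries these transcripts went against the label. The libraries labelled 12-month female replicates 1 and 4 and 6-month female replicate 3 held Ddx3y at 63.8, 16.8 and 45.6 CPM, and the libraries labelled 12-month male replicate 3 and 6-month male replicate 3 held Xist at 76.2 and 78.5 CPM. All 5 stayed in the groups that their labels gave, and the total of genes called in each comparison was also computed without them.

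Transcripts of other cell types were abundant in some libraries. The summed CPM of 12 keratinocyte markers, with a median of 2.95 over all libraries, exceeded 100 in 6 libraries and reached 11400 in 28-month female replicate 8 and 6280 in CaAKG replicate 8. The sum of 14 neutrophil markers, with a median of 3.46, exceeded 100 in 4 libraries: 1810 in 28-month female replicate 10, 529 in 28-month female replicate 12, 961 in CaAKG replicate 7 and 245 in CaAKG replicate 6.

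**Figure D1:**
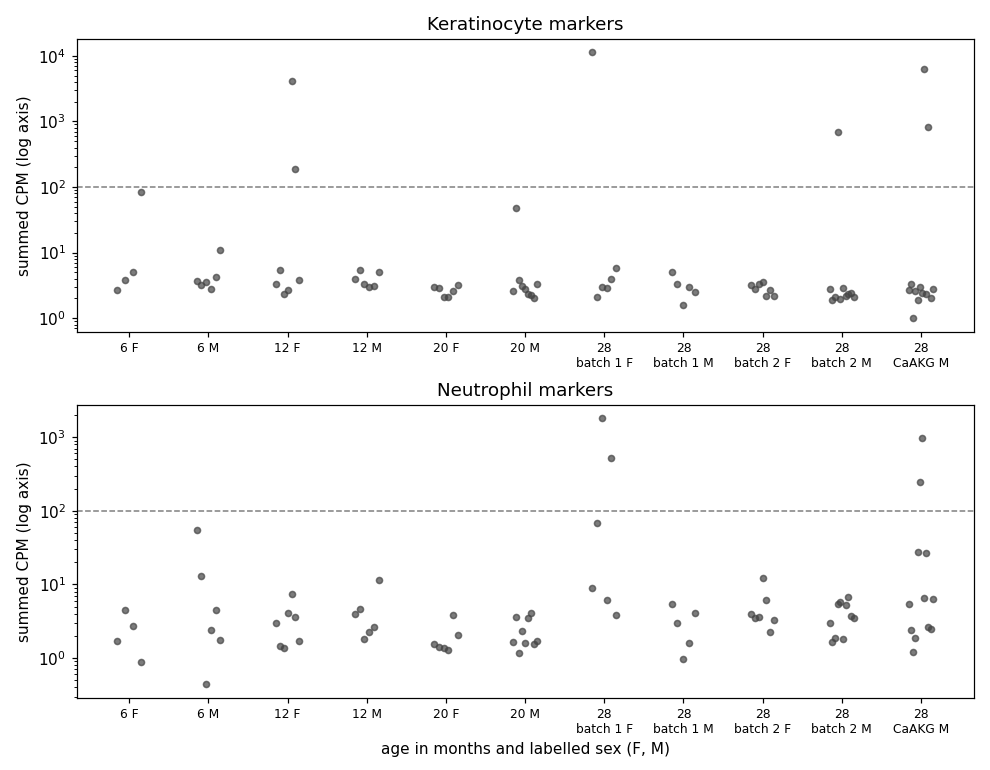
Summed CPM of the keratinocyte and the neutrophil markers in each library (points, log axis), by age in months, batch and labelled sex; the dashed line marks 100 CPM. Of the 78 libraries, 6 lie above the line for keratinocyte markers and 4 for neutrophil markers.

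Between 6 and 28 months in females, genes of mitochondrial energy supply fell together. Of 55 nuclear-encoded subunits of oxidative phosphorylation, 52 fell and 0 rose (53 fell adjusted over the list alone), with a median log2 fold change of -0.71. Atp5g1, a subunit c gene of ATP synthase (chromosome 11, 96068852 to 96075670, ENSMUSG00000006057), went from 990 ± 300 CPM (SD, n = 4) to 515 ± 135 CPM (SD, n = 6), a log2 fold change of -0.94 (SE 0.18, adjusted p = 0.00038). The highest 6-month value, 1415 CPM, was in the library labelled female replicate 3, which goes against its sex label. Without that library Atp5g1 was at -0.73 (edgeR QL adjusted p = 0.013). Of 23 tricarboxylic acid cycle genes 14 fell (15 adjusted over the list alone). Among them were the succinate dehydrogenase subunits Sdhd, Sdhc and Sdhb and the isocitrate dehydrogenase subunit Idh3b, at log2 fold changes of -0.79, -0.66, -0.74 and -0.61. Of 15 slow-fibre genes 5 fell (5 adjusted over the list alone). The slow myosin light chains Myl3 and Myl2 were at -0.91 (SE 0.14) and -0.92 (SE 0.18), while the slow myosin heavy chain Myh7 was at 0.22 (SE 0.32, adjusted p = 0.66). By camera the 3 lists had adjusted p of 8.7e-35, 3.2e-09 and 0.0013, and adjusted p = 0.49 with an estimated correlation for each of them. Lower genes in this comparison were shorter (median 2021 bases, against 4554 for higher genes), and with length and GC offsets 29 subunits, 5 cycle genes and 2 slow-fibre genes fell.

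Genes that respond to loss of nerve supply and genes of muscle breakdown rose in the same comparison. Of 24 genes of the denervation and synapse list 9 rose (13 adjusted over the list alone). Musk, the receptor kinase of the neuromuscular junction, was at a log2 fold change of 0.90 (SE 0.25), the stress gene Gadd45a at 2.44 (SE 0.70), the acetylcholine receptor subunit Chrnb1 at 0.91 (SE 0.27) and the adhesion molecule Ncam1 at 1.13 (SE 0.35). Of 26 atrophy and FoxO genes 9 rose and 1 fell (10 rose and 1 fell adjusted over the list alone). Among them were Ddit4, an inhibitor of mTORC1, at 2.14 (SE 0.48), the muscle ubiquitin ligase Fbxo32 at 1.03 (SE 0.25), and the transcription factors Foxo3 and Foxo1 at 1.00 and 1.28. These 2 lists had camera adjusted p of 0.0047 and 0.0014, and adjusted p = 0.49 with an estimated correlation for both. When 1 library was left out the lowest values of Gadd45a, Chrnb1 and Ncam1 were 1.84, 0.55 and 0.91 (without 28-month female replicates 11 and 9 and 6-month female replicate 3), none past the threshold. The lowest values of Ddit4, Fbxo32, Foxo3 and Foxo1, all without 28-month female replicate 9, were 1.54, 0.59, 0.73 and 1.16, each still past the threshold. Without the libraries against their sex label or with skin or marrow transcripts, 11 atrophy genes and 7 denervation genes rose. That fit keeps replicate 9.

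Immune and proliferation genes were also higher in 28-month females. Of 37 interferon and antigen presentation genes 13 rose (27 adjusted over the list alone). These included the class I molecules H2-D1 and H2-K1 at log2 fold changes of 1.13 (SE 0.27) and 1.12 (SE 0.30) and the interferon-induced Ifit3 and Ifit1 at 1.48 and 1.62. All 14 neutrophil markers rose (14 adjusted over the list alone), as did 15 of 25 cell cycle genes (20 adjusted over the list alone). Among these were the replication helicase subunits Mcm6, Mcm5 and Mcm3 at 1.23, 2.62 and 1.26 and the proliferation marker Mki67 at 5.12. In the order given, camera adjusted p was 2.5e-09, 0.0014 and 0.00049, with adjusted p = 0.49, 0.51 and 0.51 with an estimated correlation. The 28-month female libraries with 1810 and 529 CPM of neutrophil markers belong to this group, together with 1 library with skin transcripts. Without these 3 and the library labelled 6-month female replicate 3, which leaves 3 libraries against 3, 0 interferon genes, 1 neutrophil marker and 0 cell cycle genes passed (edgeR QL; 4153 of all genes at an unadjusted p under 0.05). The list medians were then 0.51, 2.63 and -0.27, against 1.12, 7.32 and 2.40. Mcm3 did not pass without replicate 10 alone (0.74, adjusted p = 0.085).

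The genes with the largest rises in females were near or at 0 at 6 months, so their levels are given in place of folds. Mpo, the myeloperoxidase of neutrophil granules, was at 23.8 ± 41 CPM (SD, n = 6) at 28 months and 0 at 6 months. Ngp, another neutrophil granule protein, was at 54.7 ± 96 CPM against 0.00344 CPM, and Cd177, Prg2 and Hemgn, genes of granulocytes and blood-forming cells, were at 7.33, 5.72 and 5.55 CPM against 0. The epidermal genes Krt2, Aqp3 and Tgm3 had means of 222, 9.57 and 6.49 CPM; replicate 8 held 1330, 57.4 and 38.9 CPM and the other 5 libraries 0. The largest falls were Eif2s3y, Ddx3y, Uty and Kdm5d, Y-linked genes seen at 6 months in the library labelled female replicate 3, followed by the transporter-family gene Slc15a5 at -2.14, Spinkl at -1.86, Cilp2, a cartilage intermediate layer protein gene, at -1.70 and Pcp4, a calmodulin regulator, at -1.59. Slc15a5 was at -0.31 without the library labelled 6-month female replicate 3. Of the genes in this paragraph only Cd177 passed without each single library in turn.

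In total 1789 genes rose and 1634 fell between 6 and 28 months in females (edgeR QL, adjusted p under 0.05). The count was 1375 without the library labelled 6-month female replicate 3, 2215 without replicate 2, and 1337 without all libraries doubted above. With only the compared groups in the edgeR QL fit 0 genes passed (3548 at an unadjusted p under 0.05), against 1277 in the test against a fold of 1.2 and 1505 with length and GC offsets.

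Between 6 and 28 months in males, vessel-wall genes rose. Of 17 endothelial markers 14 rose (14 adjusted over the list alone) and of 13 smooth muscle and pericyte markers 8 rose (9 adjusted over the list alone), with median log2 fold changes of 0.92 and 0.78. Cdh5, the cadherin of endothelial junctions (chromosome 8, 104101625 to 104144511, ENSMUSG00000031871), went from 20.8 ± 4.88 CPM (SD, n = 6) to 54.7 ± 10.6 CPM (SD, n = 5), a log2 fold change of 1.40 (SE 0.24, adjusted p = 7.4e-05). The endothelial phosphatase Ptprb, the VEGF receptor Flt1 and the water channel Aqp1 were at 1.27, 1.35 and 1.06. Myh11, the smooth muscle myosin heavy chain (chromosome 16, 14194535 to 14291372, ENSMUSG00000018830), went from 7.37 ± 1.41 to 25.7 ± 5.76 CPM (log2 fold change 1.80, SE 0.26, adjusted p = 3.3e-06), with Mcam, Rgs5 and Acta2 at 1.21, 0.95 and 0.87. For the 2 vessel lists camera adjusted p was 1.8e-12 and 1.3e-06, and adjusted p = 0.12 and 0.073 with an estimated correlation. With length and GC offsets 9 endothelial and 5 smooth muscle markers passed. The rise of Cdh5 did not grow steadily with age in males. At 20 months it was at 97.7 to 121 CPM, above the 43.4 to 64.8 CPM at 28 months in batch 1. Control males of 28 months in batch 2 held 46.5 to 109 CPM. The mice of 6 and 20 months came from different suppliers.

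Genes of respiration, translation and protein folding fell in 28-month males. Of 55 oxidative phosphorylation subunits 33 fell (42 adjusted over the list alone). Of these, Atp5g1 was at a log2 fold change of -0.72 (SE 0.17), Cox5a at -0.58, Uqcrq at -0.84 and Cox6a2 at -0.56. Of 48 ribosomal protein genes 24 fell (37 adjusted over the list alone). Of these, Rps3 was at -0.63, Rps2 at -0.73, Rpl15 at -0.55 and Rplp1 at -0.68. Of 22 heat shock and chaperone genes 10 fell (17 adjusted over the list alone). The mitochondrial chaperonin Hspe1 was at -0.84 (SE 0.15), and Dnaja1, Hspa1l and Hsph1 at -0.75, -0.79 and -0.86. Of 25 unfolded protein and integrated stress response genes 8 fell (9 adjusted over the list alone). The stress transcription factors Atf4 and Ddit3 were at -0.69 and -0.88 and the endoplasmic reticulum proteins Creld2 and Manf at -0.91 and -0.86. Camera gave the 4 lists adjusted p of 3.3e-16, 8.5e-15, 4.7e-09 and 0.00064, and adjusted p = 0.52, 0.52, 0.21 and 0.33 with an estimated correlation. Subunit and ribosomal transcripts are short, with median lengths of 1363 and 1200 bases against 3079 for all genes, and with length and GC offsets 8 subunits and 7 ribosomal protein genes fell.

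Of the 24 denervation and synapse genes 7 rose and 1 fell in males (12 rose and 1 fell adjusted over the list alone). The embryonic myosin Myh3, Gadd45a and the fetal acetylcholine receptor subunit Chrng were at log2 fold changes of 2.04 (SE 0.46), 2.39 (SE 0.62) and 3.52 (SE 0.99), and Rapsn, which clusters acetylcholine receptors, fell by 0.64 (SE 0.13). Without 28-month male replicate 15 Gadd45a and Chrng were at 1.10 and 1.73 and did not pass. Of 18 adipocyte markers 7 rose (12 adjusted over the list alone). The lipase Lipe was at 1.04, the hormone gene Lep at 3.82, the fatty acid carrier Fabp4 at 0.71 and the carbonic anhydrase Car3 at 0.62. The camera adjusted p values were 0.0049 and 0.0016, and adjusted p = 0.52 with an estimated correlation for both lists. The largest rises were the keratins Krt18 at 4.58 and Krt8 at 3.71, Prr32 at 3.87, Lep, the aldehyde dehydrogenase Aldh3a1 at 3.75, the potassium channel Kcnj3 at 3.66, Nnat at 3.58 and Ano3 at 3.57. The largest falls included Xist, seen at 84.9 CPM in the library labelled 6-month male replicate 3 and at 0 in the other 6-month males, the arginase Arg1 at -6.20, the chemokines Ccl7 and Ccl2 at -4.46 and -4.17, the amino acid transporter Slc6a19 at -3.54, AI662270 at -2.49 and the cytokine signalling inhibitor Cish at -2.41. Single libraries carried most of these calls. Replicate 1 at 6 months held 503 CPM of macrophage markers against 95 to 152 in the other 5, and without it Arg1, Ccl7, Ccl2 and Slc6a19 were at 0.23, -1.52, -0.35 and -0.85, with adjusted p of 0.97, 0.28, 0.82 and 0.64. Without 28-month replicate 15 Krt18, Aldh3a1 and Krt8 were at 3.16, 2.08 and 3.03, and without replicate 11 Lep, Nnat and Fabp4 at 2.62, 1.73 and 0.32, none past the threshold. Car3, AI662270 and Cish also lost the call without 1 library, and Prr32, Kcnj3 and Ano3 kept it without each single library.

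In total 1232 genes rose and 1707 fell between 6 and 28 months in males (edgeR QL). The count was 1575 with the fast-fibre and adipocyte list means as covariates, 1561 with length and GC offsets, 751 in the test against a fold of 1.2, and 5349 with limma-voom and quality weights.

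The changes of the 2 sexes between 6 and 28 months overlapped in direction. In both sexes 411 genes rose, against 121 for independent lists of these sizes, and 938 fell, against 153, while 6 genes passed in opposite directions. Across all genes the 2 changes had r = 0.047 (Spearman 0.332), and both ran with transcript length (Spearman 0.287 in females and 0.322 in males). Without the libraries doubted above 269 genes rose in both, against 79, 332 fell in both, against 81, and 19 passed in opposite directions, with r = 0.143 (Spearman 0.236). A direct test of the difference, the sex by age interaction, called 20 genes higher and 31 lower in the male change (edgeR QL). With the smallest p among these, the angiotensin receptor Agtr1a was at 1.71 and Gas2 at 1.82, both named after their values were seen. The count was 288 with DESeq2, 217 without the libraries with skin or marrow transcripts and, by edgeR QL, 0 with only the compared groups in the fit (1397 at an unadjusted p under 0.05). It lay between 3 and 139 when single libraries were left out, as listed in the closing section.

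The 20-month groups stood furthest from the 6-month groups, and the mice of these ages came from different suppliers. Of 48 ribosomal protein genes 47 fell between 6 and 20 months in females and 47 in males (47 and 48 adjusted over the list alone), with a median log2 fold change of -1.02 in each. Of 55 oxidative phosphorylation subunits 50 fell in females and 51 in males (53 fell in each adjusted over the list alone, with 2 male rises). Rps3, a small-subunit ribosomal protein, was at -1.12 (SE 0.15) and -1.20 (SE 0.12), and Atp5g1 at -1.29 (SE 0.18) and -1.30 (SE 0.15). Of 17 endothelial markers 12 rose and 1 fell in females and 13 rose in males (the same counts adjusted over the list alone), with Cdh5 at 1.94 (SE 0.27) and 2.42 (SE 0.23) and the smooth muscle gene Myh11 at 1.86 (SE 0.29) and 2.68 (SE 0.25). Other cell markers moved with them: collagen and matrix genes rose (14 of 35 in females, 15 adjusted over the list alone; 18 in males, where 2 fell, and the same adjusted over the list alone; adjusted p = 0.92 and 0.75 with an estimated correlation), and in males 10 of 14 tendon and 11 of 18 adipocyte markers rose, with 1 of each falling, and 9 of 14 neutrophil markers fell (10, 12 and 10 adjusted over the list alone; adjusted p = 0.75, 0.75 and 0.95 with an estimated correlation). The camera adjusted p values in females were 2e-27, 2.8e-22 and 2.2e-05, and adjusted p = 0.32, 0.35 and 0.43 with an estimated correlation; in males they were 2e-28, 5e-21 and 2.2e-08, and adjusted p = 0.23, 0.29 and 0.23 with an estimated correlation. In 6-month males the neutrophil marker sums were 55.3 and 12.9 CPM in replicates 1 and 2. The other 6-month males held 0.441 to 4.5 CPM, against 1.17 to 4.03 CPM in the 20-month males. Fold changes ran with transcript length across genes (Spearman 0.545 in females and 0.5 in males, genes not being independent replicates), and with length and GC offsets 41 and 45 ribosomal protein genes, 30 and 42 subunits and 9 and 13 endothelial markers still passed. In total 3307 genes rose and 3244 fell in females and 4108 rose and 4006 fell in males (edgeR QL), or 3193 and 5672 genes with these offsets.

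**Figure D2:**
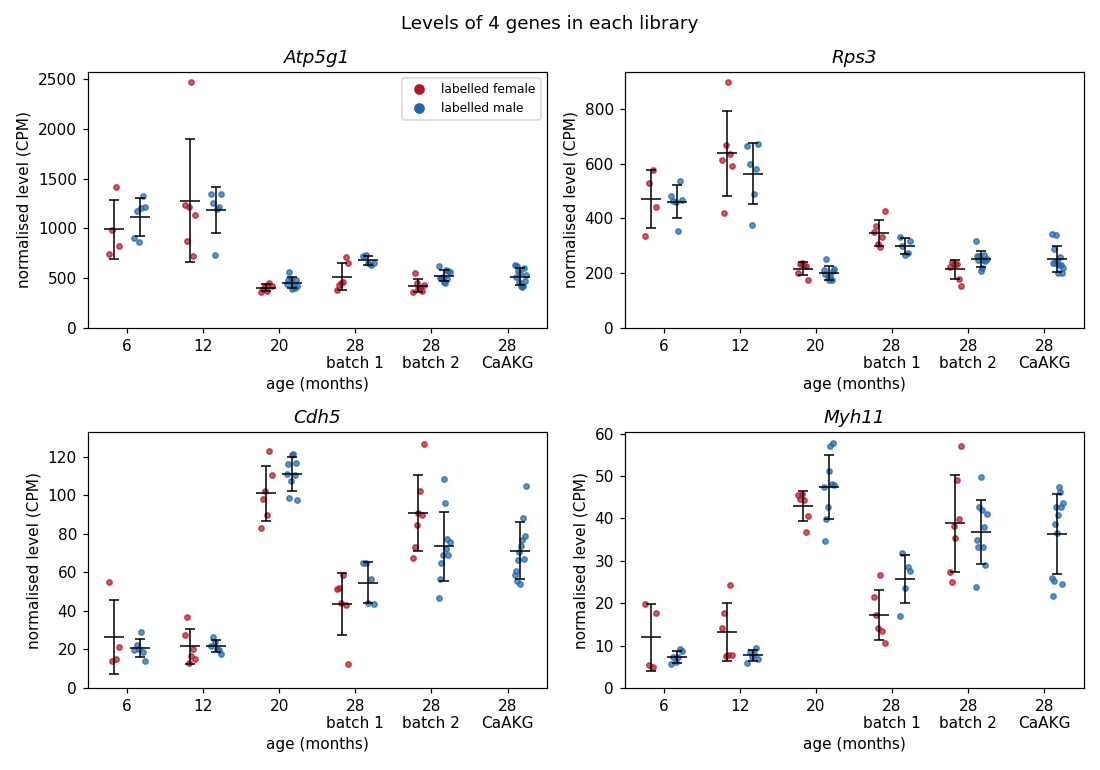
Normalised levels (CPM, linear axis from 0) of Atp5g1, Rps3, Cdh5 and Myh11 in each library (points) by age in months, batch and labelled sex; bars show the mean and SD of each group. Cdh5 went from 20.8 CPM at 6 months to 54.7 CPM at 28 months in batch 1 males.

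In batch 1, ribosomal and endothelial genes moved the other way from 20 to 28 months. Both steps share the 20-month group, so an offset of that group alone would give opposite moves. Rps3 in 28-month batch 2 control females was at 153 to 242 CPM, near the 175 to 238 CPM at 20 months. Batch 1 females at 28 months held 294 to 427 CPM. In males the values in this order were 207 to 318, 174 to 253 and 267.5 to 334 CPM. Of the 55 subunits 33 rose in males (46 adjusted over the list alone; camera adjusted p = 1.1e-15, adjusted p = 0.58 with an estimated correlation). In females 6 rose and 2 fell (3 and 1 adjusted over the list alone; adjusted p = 0.011, adjusted p = 0.73 with an estimated correlation), and the difference between the sexes was not tested. In females blood-cell and proliferation genes rose too: 14 of 14 neutrophil, 17 of 17 B and plasma cell, 9 of 10 erythroid and 9 of 17 T and NK cell markers and 22 of 25 cell cycle genes, while 9 of 14 tendon markers fell. Adjusted over the list alone, 14, 17, 9, 10 and 25 rose and 10 tendon markers fell. The estimated-correlation camera left none of these lists past the threshold (adjusted p = 0.44, 0.42, 0.55, 0.42, 0.48 and 0.31 with an estimated correlation). This group holds 28-month female replicates 8, 10 and 12 with skin or marrow transcripts, and without the libraries doubted above 7, 17, 1, 9 and 0 of these genes rose and 12 tendon markers fell. Replicate 11, which stays in that fit, held 1050 CPM of B and plasma cell markers, against 139 and 110 in replicates 9 and 13. Its T and NK cell markers were at 39.2 CPM, against 3.68 and 7.49. Of 48 ribosomal protein genes 47 rose in females and 46 in males (47 in each adjusted over the list alone), and 8 and 7 endothelial markers fell (9 in each adjusted over the list alone, with 1 male rise). Rps3 was at 0.68 (SE 0.14) and 0.57 (SE 0.13), and Cdh5 at -1.21 (SE 0.23) and -1.02 (SE 0.23). The camera adjusted p values were 2.9e-30 and 7.4e-05 in females and 7.4e-32 and 0.00049 in males, and adjusted p = 0.22, 0.42, 0.22 and 0.58 with an estimated correlation. In total 3139 genes rose and 2285 fell in females and 1495 rose and 1591 fell in males (edgeR QL). Here fold changes ran against transcript length (Spearman -0.402 and -0.497), and with length and GC offsets 31 and 11 ribosomal protein genes and 2 and 1 subunits rose and 8 and 3 endothelial markers fell. In total 2311 and 333 genes passed with these offsets, and with only the compared groups in the fit the male count was 5199.

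Between 6 and 12 months, ages from 1 supplier, genes of protein folding fell in males and ribosomal protein genes rose. Of 48 ribosomal protein genes 15 rose in males (37 adjusted over the list alone; camera adjusted p = 3e-15, adjusted p = 0.73 with an estimated correlation). In females 0 passed over all genes by edgeR QL and 43 rose adjusted over the list alone (adjusted p = 3.6e-34, adjusted p = 0.44 with an estimated correlation). Of 13 genes of the mitochondrial genome 11 rose in females adjusted over the list alone and 0 over all genes (adjusted p = 1.3e-08, adjusted p = 0.44 with an estimated correlation). Replicate 4 at 12 months, one of the libraries against their sex label, held 46.5% of its counts in these genes, and without it 0 of the 13 rose in either way. The difference between the sexes over this span was not tested, and the female groups hold 3 of the 5 libraries against their sex label. In males 12 of 22 heat shock genes fell (17 adjusted over the list alone; camera adjusted p = 2.3e-15, adjusted p = 0.06 with an estimated correlation), and 12 of 25 unfolded protein and integrated stress response genes fell (14 adjusted over the list alone; adjusted p = 2.8e-05, adjusted p = 0.21 with an estimated correlation). In total 547 genes rose and 1233 fell in males and 7 rose and 34 fell in females (edgeR QL). Fold changes ran against transcript length (Spearman -0.201 in males and -0.262 in females). Ribosomal transcripts are short, with a median of 1200 bases against 3079 for all genes. With length and GC offsets 910 genes passed in males and 6 in females. The male count was 3172 without the libraries against their sex label, and the female count was 0 by edgeR QL without all libraries doubted above (2209 at an unadjusted p under 0.05), 366 with limma-voom, 105 with DESeq2, and 1, 6, 307 and 3 without 6-month female replicates 1, 2, 3 and 4 in turn.

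The fibre-type and senescence genes chosen in advance passed in few comparisons. Myh2, the IIa myosin heavy chain, rose between 6 and 20 months in females by 0.80 (SE 0.25, adjusted p = 0.0089) and in males by 0.85 (SE 0.21, adjusted p = 0.00044), and between 6 and 28 months in males by 0.65 (SE 0.23, adjusted p = 0.042; not past the threshold without any 1 of 9 of the 11 libraries), with 0.32 (SE 0.25, adjusted p = 0.38) in females. The slow Myh7 rose between 6 and 20 months by 0.83 (SE 0.33) and 0.62 (SE 0.26). Cdkn1a, an inhibitor of cell division, fell between 6 and 20 months in males by 0.97 (SE 0.36, adjusted p = 0.024) and was higher at 28 than at 20 months, by 1.29 (SE 0.41) in females and 1.39 (SE 0.38) in males (edgeR QL adjusted p = 0.012 and 0.0063). Male replicate 15 held Cdkn1a at 91.2 CPM against 25.5 to 36.5 in the other 4, and without it the male value was 0.92 (SE 0.39, adjusted p = 0.11). Cdkn2a and the stress hormone gene Gdf15 did not pass in any of the 12 comparisons (edgeR QL). Both were near the floor, where a change could go unseen. In 28-month batch 1 females Cdkn2a was at 0.661 CPM in replicate 10 and at 0 to 0.199 in the others. In 20-month females Gdf15 was at 1.04 CPM in replicate 1 and at 0.346 to 0.561 in the others. Cdkn2a was at 0.07 (SE 1.02) and 1.73 (SE 0.98), and Gdf15 at 0.56 (SE 0.74) and -0.97 (SE 0.71) between 6 and 28 months in females and males. The fast myosins Myh1 and Myh4 were at 0.85 (SE 0.47) and 1.19 (SE 1.67) in females and at -0.25 (SE 0.43) and 0 (SE 1.5) in males over that span, and Myh4 passed in the batch comparison alone, at -3.03 (SE 0.99). In batch 1, 28-month female replicate 9 and male replicate 13 held Myh4 at 14000 and 4900 CPM, and without these 2 it was at 0.27 (SE 0.97, adjusted p = 0.89).

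With CaAKG in the feed of 28-month males, no single gene of alpha-ketoglutarate metabolism or fatty acid oxidation passed the test. Of the 34 lists 13 passed by camera and 0 with an estimated correlation. Besides those below they included immediate early genes, interferon genes and the nuclear and mitochondrial subunits of oxidative phosphorylation, at medians of 0.30, 0.16, -0.06 and -0.19 (adjusted p = 0.00033, 0.0027, 0.0027 and 0.0027, and adjusted p = 0.76, 0.81, 0.89 and 0.76 with an estimated correlation). Of 23 genes of glutamate and alpha-ketoglutarate metabolism, 36 alpha-ketoglutarate-dependent dioxygenases and 30 fatty acid oxidation genes, 0 passed in each list (0 adjusted over each list alone). Glul, the glutamine synthetase, was at a log2 fold change of 0.49 (SE 0.18, adjusted p = 0.56), the dioxygenase Asph at -0.34 (SE 0.10, adjusted p = 0.30) and the mitochondrial coactivator Ppargc1a at -0.67 (SE 0.25, adjusted p = 0.58). The camera adjusted p values were 0.19, 0.81 and 0.00015, and adjusted p = 0.76, 0.94 and 0.76 with an estimated correlation; the fatty acid oxidation list had a median of -0.10, and the dioxygenases a median of 0, a mean of 0.06 and a test direction below 0. Myh7, Myh2, Myh1 and Myh4 were at -0.10 (SE 0.21), -0.03 (SE 0.16), 0.25 (SE 0.31) and -0.66 (SE 1.06), and Cdkn1a, Cdkn2a and Gdf15 at 0.26 (SE 0.30), -0.34 (SE 0.67) and -0.23 (SE 0.49).

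The genes that passed with CaAKG were 4 of neutrophils and their precursors or of related proteases, and 0 fell (edgeR QL; 1201 genes had an unadjusted p under 0.05, and 29 passed with DESeq2). Elane, the neutrophil elastase (chromosome 10, 79886247 to 79888215, ENSMUSG00000020125), was at 1.55 ± 4.30 CPM (SD, n = 12) against 0.00275 ± 0.00871 CPM (SD, n = 10) in controls, with an adjusted p of 0.038. Ltf, the lactoferrin of neutrophil granules, was at 12.3 ± 33.9 against 0.108 ± 0.116 CPM (adjusted p = 0.038), and the protease Ctse at 1.68 ± 5.05 against 0.0219 ± 0.0384 CPM (adjusted p = 0.044). Ctsg, a neutrophil protease named after its values were seen, was at a log2 fold change of 6.74 (SE 1.38, adjusted p = 0.038). Of the 14 neutrophil markers 2 rose (14 adjusted over the list alone; camera adjusted p = 3.4e-05, adjusted p = 0.76 with an estimated correlation), and of 25 cell cycle genes 0 rose (11 adjusted over the list alone; adjusted p = 3.7e-06, adjusted p = 0.76 with an estimated correlation), with Mki67 at 3.59 (SE 0.83, adjusted p = 0.079). CaAKG replicates 7 and 6 held 961 and 245 CPM of neutrophil markers. The lowest p among lower genes were those of Tnip3, Ptpn4 and Cyp2u1, at -3.08, -0.58 and -0.44, with adjusted p of 0.22, 0.22 and 0.23.

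The count of 4 became 0 without CaAKG replicate 6 or 7, without any single control replicate among 1, 2, 3 and 5 to 10, without the libraries with skin or marrow transcripts, and with only the compared groups in the fit. It was 77 without control replicate 4, 11 to 13 without any of the other CaAKG replicates, and 155 with the controls of both batches pooled. Across genes the CaAKG change had r = -0.106 with the change between 6 and 28 months in males, and 32 of 100 reassignments of the CaAKG and control labels gave an r at least as far from 0. Against the change between 6 and 28 months in females r was 0.683, and 0 of 100 reassignments gave an r as far from 0 (range -0.653 to 0.681). The 28-month female and the CaAKG groups both hold libraries with skin and with marrow transcripts, and without the libraries doubted above this r was 0.074. None of these changes shares a library with the CaAKG change.

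Males differed from females in fuel use and fibre genes on average over the 4 ages. Of 23 tricarboxylic acid cycle genes 13 were higher in males (17 adjusted over the list alone), of 30 fatty acid oxidation genes 10 (16 higher and 2 lower adjusted over the list alone) and of 55 oxidative phosphorylation subunits 10 (16 adjusted over the list alone). Hadh, an enzyme of beta-oxidation, was higher by 0.45 (SE 0.07, adjusted p = 5.2e-06), Acadl and Etfdh by 0.31 and 0.33, and Idh3a and Dlat by 0.34 and 0.29. Of 15 slow-fibre genes 7 were lower in males (8 lower and 1 higher adjusted over the list alone), with Tnnc1, Tnni1, Tnnt1 and Tpm3 at -0.45, -0.45, -0.34 and -0.36 and Myh7 at -0.51 (SE 0.14, adjusted p = 0.03), and of 16 fast-fibre genes Tnni2, Tnnc2 and Tnnt3 were higher by 0.37, 0.32 and 0.32 (3 adjusted over the list alone). Of 37 interferon and antigen presentation genes 6 were lower in males (30 adjusted over the list alone). Ifit1 was at -0.78, Irf9 at -0.46, Oas1a at -0.84 and Ifi44 at -1.02. The camera adjusted p values of the 6 lists, in this order, were 3.5e-18, 1.6e-09, 6.2e-14, 1.4e-07, 0.013 and 1.2e-15, and adjusted p = 0.29, 0.39, 0.58, 0.32, 0.58 and 0.29 with an estimated correlation. With length and GC offsets 22 of the genes considered for naming and called between the sexes kept the call and 18 lost it.

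Outside these lists, the largest sex differences were Y-linked Ddx3y, Eif2s3y, Uty and Kdm5d, higher in males by 8.29, 7.85, 7.17 and 6.98, and Xist, lower by a log2 value of -7.76. These sizes are not exact. The groups hold the libraries against their sex label, and in libraries that match it the other sex had medians of 0 CPM. Slc15a5, the complement gene C7, Kcnj3 and the calcium release channel Ryr2 were higher in males by 2.34, 2.27, 1.91 and 1.87, and the aldo-keto reductase Akr1cl and the bone matrix gene Ibsp were at -6.15 and -5.59. The remaining large differences, Gdpd2, Col17a1, Krt78, Klk7 and Dsp at -5.36, -4.92, -4.88, -4.86 and -4.49, include epidermal genes, and the libraries labelled 28-month female replicate 8 and 12-month female replicate 5 held 11400 and 4080 CPM of keratinocyte markers. The groups compared also hold 28-month female replicate 10, with 1810 CPM of neutrophil markers. Without all libraries doubted above, 33 of the named genes called between the sexes kept direction and call. A further 6 lost the call and 1, Klk7, reversed. In total 351 genes were higher and 253 lower in males (edgeR QL). The count was 1670 without the libraries against their sex label, 1728 without all libraries doubted above, 268 with length and GC offsets, 51 against a fold of 1.2, 370 with only the compared groups in the fit and 1554 with limma-voom.

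The batches differed at equal age and treatment. Between 28-month controls of batch 2 and batch 1, 46 of 48 ribosomal protein genes were lower (48 adjusted over the list alone; camera adjusted p = 1.1e-32, adjusted p = 0.25 with an estimated correlation) and 6 of 17 endothelial markers were higher (8 adjusted over the list alone; adjusted p = 0.00056, adjusted p = 0.61 with an estimated correlation). Rps3 was at -0.47 (SE 0.09) and Cdh5 at 0.74 (SE 0.16). In total 1696 genes were higher and 2051 lower in batch 2 (edgeR QL), or 612 with length and GC offsets.

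**Figure D3:**
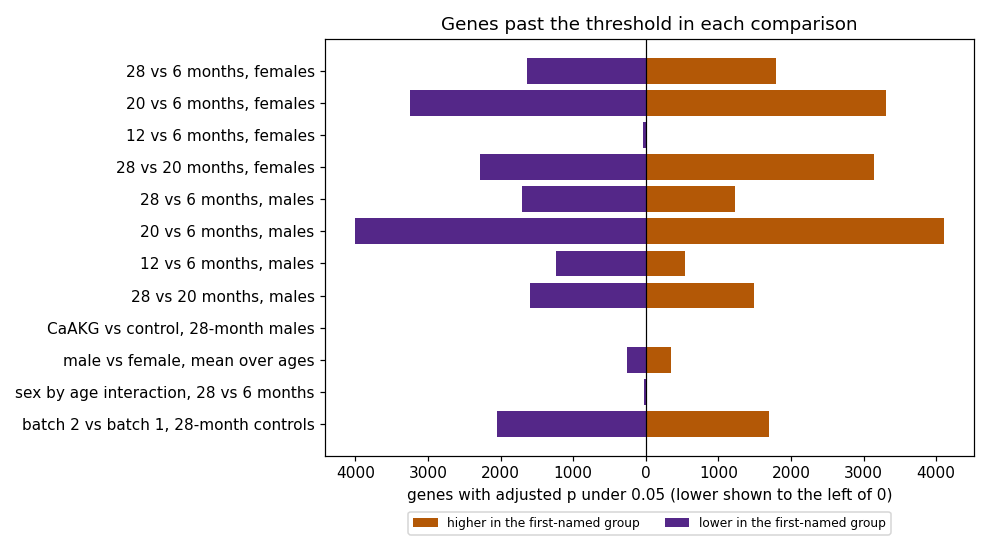
Genes with an adjusted p under 0.05 in each of the 12 comparisons (edgeR QL), with genes higher in the first-named group to the right of 0 and genes lower to the left; the axis counts genes on a linear scale. The changes between 6 and 20 months hold the most genes, 6551 in females and 8114 in males, and the CaAKG comparison holds 4.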

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

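The tests of the batch axis, of blood-forming cells and of the sex labels were chosen after the results were seen, as were the fits without named libraries and with length and GC offsets; the length test, the Nnt test and the regroupings were written before.

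The change between 6 and 20 months took in ribosomal, respiratory and vessel genes in both sexes, with 6551 genes in females and 8114 in males. With length and GC offsets 2602 and 4630 of these genes were still called in the same direction. The bounds written before leave the length test undecided. Spearman correlations with length, 0.545 in females and 0.5 in males, passed the bound for length as the cause. The cut in calls passed its bound in females (6551 to 3193) and not in males (8114 to 5672). The opposite bound, over 0.75 of the calls left, was met in neither sex. A bound of over 0.25 of the calls shared was set after the counts were seen, so no conclusion rests on it. The fold changes correlated with the batch 2 against batch 1 change at r = 0.331 in females and 0.231 in males, so a trend of RNA quality or library preparation and a change with age cannot be told apart here. Nnt, deleted in part in C57BL/6J and not in C57BL/6N, had means of 130 CPM (23 libraries, with the animal tag that 2 of them share counted as 2) at 6 and 12 months and 131 CPM (43 libraries) at 20 and 28 months, a ratio of 1.01. This argues against the deletion being carried by 1 of these sets of ages alone, though 1 of the older libraries held Nnt at 0. Substrains that do not differ at Nnt cannot be told apart by it. Supplier, housing and age remain open together, as they changed at once.

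The genes higher with CaAKG are of blood-forming cells, and marrow transcripts in single libraries may account for them. Without CaAKG replicate 7, the highest in neutrophil markers, 0 genes passed (edgeR QL; 1003 at an unadjusted p under 0.05) and the called genes had a median log2 fold change of 4.5, but 10 of the 21 other single libraries also end every call when left out, so this test decides nothing. Without all libraries with skin or marrow transcripts Elane and Ltf were at 3.35 (SE 1.11) and 1.93 (SE 1.03), against 8.11 and 6.82. Ctse and Ctsg were then at 1.21 (SE 1) and 1.72 (SE 1.08), against 6 and 6.74. None of these 4 genes passed in that fit (edgeR QL). The 2 libraries highest in erythroid markers, replicates 7 and 5, held 82.1% of the summed CPM of the called genes, under the 90% set for the test, with 0 genes called without them (1013 at an unadjusted p under 0.05). That pair leaves out CaAKG replicate 6, with 245 CPM of neutrophil markers against 27.7 in replicate 5. The missed bound therefore decides nothing about marrow. Of the 4 called genes Elane, Ltf, Ctse and Ctsg, the level was above the highest control in 4 to 5 of the 12 CaAKG libraries each. A response of blood-forming cells to CaAKG and marrow left on the muscle at dissection cannot be told apart, and 38 of 100 regroupings gave as many genes.

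The 5 libraries whose sex transcripts went against their label held the labelled sex's transcript at 0.116% or less of the level in matching libraries, which argues against a mixture of both sexes in 1 tube. Their other-sex transcript was at least 0.329 times the median of that sex at the same age, which a wrong label or exchanged tubes would give. Both 6-month groups and both 12-month groups hold such libraries, so an exchange within an age could produce 4 of them, and no record in the sources used here tells which. A biological explanation was not tested.

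In 49 of 160 group levels 1 library stood apart from the rest of its group by the gap to the nearest library (Dixon's test, 1 in 20). The 8 expected by chance is no valid reference here. Some levels are of genes named for high values in single libraries, some are 0 in all but 1 library, and several repeat 1 library. For Myh4, 1 library stood above the others at 6150 CPM in 6-month females, 404 in 12-month females, 3070 in 20-month females, 14000 in 28-month batch 1 females and 4900 in 28-month batch 1 males. Myh7 was at 6280 CPM in 28-month batch 2 male replicate 1 against 8790 to 11500 in the others. Cdkn2a reached 0.341 CPM in 12-month male replicate 1 and 0.661 in 28-month female replicate 10, Cdkn1a 42 in 12-month male replicate 3 and 91.2 in 28-month male replicate 15, and Gdf15 1.04 in 20-month female replicate 1.

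In the library labelled 6-month female replicate 3, Xist was at 0 CPM and Ddx3y, Eif2s3y, Kdm5d and Uty at 51.6, 58.6, 11.7 and 12.7. In the libraries labelled 6-month male replicate 3 and 12-month male replicate 3, Xist was at 84.9 and 79.3 CPM, with Ddx3y, Eif2s3y, Kdm5d and Uty at 0 in both.

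Among epidermal genes, 28-month female replicate 8 held Krt2 at 1330, Aqp3 at 57.4 and Tgm3 at 38.9 CPM, and 6-month female replicate 4 held Krt2 at 0.611 CPM. Among blood-cell genes, 28-month female replicate 10 held Cd177 at 34.1 and Hemgn at 27.7 CPM, 6-month female replicate 2 Ngp at 0.0138, control male replicate 8 Elane, Ltf and Ctse at 0.0275, 0.413 and 0.11, and control male replicate 10 Ctsg at 0.0322. The keratinocyte marker sum stood out at 82.9 CPM in 6-month female replicate 4, 11.1 in 6-month male replicate 6, 4080 in 12-month female replicate 5, 47.8 in 20-month male replicate 2, 11400 in 28-month female replicate 8 and 686 in 28-month male replicate 4. The neutrophil marker sum stood out at 55.3 CPM in 6-month male replicate 1, 11.4 in 12-month male replicate 6, 3.82 in 20-month female replicate 5, 1810 in 28-month female replicate 10 and 12.2 in 28-month female replicate 4.

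Total counts (x 1e6) stood out at 112 in 12-month female replicate 6, the sum of 2 libraries, 59.4 in 28-month female replicate 13 and 70.5 in 28-month male replicate 6. The mitochondrial genome held 46.5% of the counts in 12-month female replicate 4, against 16% to 23% in the other 12-month females.

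By the interaction test 51 genes passed for a change between 6 and 28 months that differs between the sexes, but 13 of 100 regroupings called as many, so chance is not excluded. As the male minus the female log2 change, Mcm5 was at -3.73, Lcn2 at -8, Kcnj3 at 4.21, Ltf at -13.56, Cd177 at -15.58, S100a8 at -9.6 and S100a9 at -10.19, and Y-linked Kdm5d, Uty, Ddx3y and Eif2s3y at 10.35, 10.28, 12.41 and 12.38. The Y-linked genes were present at 6 months in the library labelled female replicate 3, and 28-month female replicates 10 and 12 held 1810 and 529 CPM of neutrophil markers. As fitted folds against levels at or near 0 these depend on the prior count.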

How the results depend on the processing

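The alternatives without named libraries and with length and GC offsets were chosen after the data were seen; the others were set before. Of the counts and the r, 168 values stayed within the set range of the reported one, 118 moved beyond it and 4 reversed; of the values of single genes and lists, 1166 kept direction and side of the threshold, 215 lost the threshold, 16 gained it and 27 reversed. Where no reason is given the cause was not tested. Fewer libraries, groups or genes in the fit leave fewer degrees of freedom or tests by construction, but this alone does not account for the moves. With only the compared groups in the fit, the count rose from 6551 to 8270 for 20 against 6 months in females. For 28 against 6 months in females it fell from 3423 to 0.

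With DESeq2 the counts were 105 for 12 against 6 months in females, 29 for CaAKG and 288 for the interaction (55 higher, 233 lower, against 20 and 31). With limma-voom they were 366 for 12 against 6 months in females, 5349, 3160 and 6563 in males for 28 against 6, 12 against 6 and 28 against 20 months, 9 for CaAKG and 1554 for sex. RLE factors gave 6 for 12 against 6 months in females and 8 for CaAKG. Leaving out the mitochondrial genome gave 11 and 8, no filter 4 for 12 against 6 months in females and 3 for the interaction, and a minimum count of 50 gave 7 for CaAKG. With only the compared groups in the fit the counts by edgeR QL were 0 for 28 against 6 months in females (3548 at an unadjusted p under 0.05), 0 for 12 against 6 months in females (374), 524 and 5199 in males for 12 against 6 and 28 against 20 months, 0 for CaAKG (1192), 370 for sex and 0 for the interaction (1397).

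The replicate numbers were also run as a replicate block, though they pair nothing: 228 pairs of libraries with the same number had a median correlation of 0.004, against 0 in 2439 other pairs. With the replicate block the counts were 1068, 13 and 3347 in females for 28 against 6, 12 against 6 and 28 against 20 months, 348 and 872 in males for 28 against 6 and 28 against 20 months, 0 for CaAKG (916 at an unadjusted p under 0.05), 187 for sex and 1122 for batch. With this block Myh2 was at -0.11 and -0.05 for 28 against 6 months in females and males, Myh4 and Bbox1 at 0.27 and -0.26 with CaAKG, and Cdkn2a at 0.1 between the sexes.

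With fast-fibre and adipocyte means as covariates the counts were 1575 for 28 against 6 months in males, 0 for CaAKG (1259 at an unadjusted p under 0.05) and 154 for the interaction. Against a fold of 1.2 they were 1277, 3 and 2777 in females and 751, 277 and 684 in males for 28 against 6, 12 against 6 and 28 against 20 months, 51 for sex, 2 for the interaction and 256 for batch. For CaAKG, keeping the libraries of 1 animal tag apart gave 8, and pooling the controls of both batches 155.

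Without the libraries against their sex label the counts were 1918 and 19 in females for 28 against 6 and 12 against 6 months, 3172 in males for 12 against 6 months, 0 for CaAKG (1406 at an unadjusted p under 0.05) and 1670 for sex. Without the libraries with skin or marrow transcripts they were 1978 for 28 against 6 months in females, 0 for CaAKG (682) and 217 for the interaction. Without both sets they were 1337 and 0 (2209) in females for 28 against 6 and 12 against 6 months, 3549 in males for 12 against 6 months, 0 for CaAKG (874), 1728 for sex and 365 for the interaction. With length and GC offsets they were 1505, 3193, 6 and 2311 in females for 28 against 6, 20 against 6, 12 against 6 and 28 against 20 months, 1561, 910 and 333 in males for 28 against 6, 12 against 6 and 28 against 20 months, 268 for sex and 612 for batch.

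Leaving out 1 library gave 1375 (without 6-month female replicate 3) to 4407 genes for 28 against 6 months in females, with 2215 without 6-month female replicate 2, and 1 to 307 for 12 against 6 months in females (1, 6, 307 and 3 without 6-month female replicates 1 to 4). CaAKG gave 0 to 77: 0 (985 to 1282 at an unadjusted p under 0.05) without CaAKG replicate 6 or 7 or any control but replicate 4, 77 without control replicate 4, and 11 to 13 without any other CaAKG replicate. The interaction gave 3 to 139. It was 3 without 28-month male replicate 12, 6-month female replicate 3 or 6-month male replicate 1, and 4, 7 and 20 without 28-month male replicates 14, 15 and 13. It was 12 and 19 without 6-month female replicates 2 and 4, 103, 30, 79, 13 and 139 without 28-month female replicates 8 and 10 to 13, 86, 105, 104 and 102 without 6-month male replicates 2 and 4 to 6, and between 105 and 139 without 6-month male replicate 3.

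With an estimated correlation 0 lists passed in each of 28 against 6 months in females and in males, CaAKG and sex, against 22, 12, 13 and 17. Without both sets of libraries the direction turned for cell cycle in 28 against 6 months in females (adjusted p = 0.34) and for the dioxygenases with CaAKG (adjusted p = 0.98). Of single genes for 28 against 6 months in females, Krt2 was at -0.47 with covariates and -5.87 without both sets, Myh7 at -0.1 with length and GC offsets, and Cdkn2a at -0.93 with limma-voom, -0.45 with covariates and -1.57 without both sets. Myh4 in the batch comparison was at 0.27 without 28-month female replicate 9 and male replicate 13. In males Arg1 was at 0.23 without 6-month male replicate 1. Of the genes past the threshold and considered for naming, 58 in females and 49 in males for 28 against 6 months lost the call without at least 1 library. Myh1 was at 0.44 with covariates, and Myh4 at 0 with DESeq2 and with RLE and 0.01 with covariates. With CaAKG Myh4 was at 0.18 with covariates, Cdkn1a at -0.05 with limma-voom, and Gdf15 and Bbox1 at 0.07 and -0.17 without both sets. Between the sexes Klk7, Myh4 and Cdkn2a were at 0.16, 0.31 and 0.14 without both sets, and Cdkn2a at 0.01 with limma-voom. The r of the CaAKG and age changes, -0.106, was 0.033 as a rank correlation, 0.087 over the genes called with age and 0.683 against the female age change (0 of 100 reassignments as far from 0, range -0.653 to 0.681), which became 0.074 (3 of 100) without both sets of libraries.

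Of 100 splits of the same libraries into groups of these sizes, the real one included, 3 gave as many genes for 28 against 6 months in females (3423, highest other 4684) and 3 for 12 against 6 months in males (1780, 1948). The real split alone, 1 of 100, did so for 20 against 6 (6551, 4081) and 28 against 20 months in females (5424, 2829). It also did so for 28 against 6 (2939, 2733), 20 against 6 (8114, 4954) and 28 against 20 months in males (3086, 592), for sex (604, 196) and for batch (3747, 296). For these, a chance split as the source of the count is argued against, at no finer than 1 in 100. Every split used the dispersions of the real grouping, and the splits do not weigh supplier, RNA quality or admixed cells. Chance is not excluded for 12 against 6 months in females (34 splits, 41 against 2786), CaAKG (38 splits, 4 against 473) and the interaction (13 splits, 51 against 670). There the highest other split called several times the real count, and the median other split 11, 0 and 0 genes. The cause of this was not tested. Depth limits genes under a few CPM.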

Other observations

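The lists and the comparison below were chosen for description after their values were seen, from the lists set before. In 28-month females other blood-cell genes rose with the neutrophil markers: 9 of 17 B and plasma cell markers (11 adjusted over the list alone, median log2 fold change 3.7) and 8 of 10 erythroid markers (8 adjusted over the list alone, median 3.88) rose between 6 and 28 months, with camera adjusted p of 0.0014 and 0.067, and adjusted p = 0.51 and 0.53 with an estimated correlation. Single libraries held most of these transcripts: the erythroid sums were 11000 and 1790 CPM in replicates 10 and 12, against 286 to 441 in the other 4, and the B and plasma cell sums 1550 and 1050 CPM in replicates 10 and 11, against 110 to 200. Without the libraries against their sex label or with skin or marrow transcripts 5 B and plasma cell markers and 0 erythroid markers rose (edgeR QL), with replicate 11 kept. In males 0 of 17 and 0 of 10 rose by edgeR QL. Of 25 immediate early genes, transcribed within minutes of a stimulus, 6 rose in females (6 adjusted over the list alone; adjusted p = 0.00041, adjusted p = 0.49 with an estimated correlation). Of 30 fatty acid oxidation genes 13 fell and 3 rose in females (15 and 3 adjusted over the list alone; adjusted p = 0.0014, adjusted p = 0.51 with an estimated correlation), and 3 rose and 0 fell in males (2 rose adjusted over the list alone; adjusted p = 0.062).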
